A study of Mus musculus with 48 samples.

How the data were processed

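Poly-A selected RNA was sequenced from 48 libraries of primary mouse cells, 12 from each of 4 mouse lines that carry a Cre-dependent BERKY3 biosensor. Per the labels' protocols, cells of heterozygous mice were plated at 430000 (astrocytes) or 160000 (lung fibroblasts) per well. They were given an adeno-associated virus with Cre or an empty one, diluted 500-fold for astrocytes and 1000-fold for fibroblasts. Agonist or fresh medium followed for 90 min.

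The values are raw read counts per gene, in 1 table per line, as deposited by the authors. Per the submitters' processing notes, reads were trimmed with fastp, aligned with Subread to GRCm39 and counted with featureCounts. The notes used here give no tool versions, gene annotation or strandedness, so counts of genes that overlap another gene, on either strand, are uncertain. All values were whole numbers of 0 or more, and each table held 50764 gene entries including the biosensor sequence. The 13 mitochondrially encoded genes held 0 counts in every library, so no mitochondrial share could be used as a sign of RNA quality. The local gene annotation is of an earlier build, so no coordinates are printed and it served only to find genes that overlap a named gene. Besides those marked where they are reported, the named genes that overlap another are Aurka, Eda2r, Hbegf, Hgf, Hspa5, Il6, Insig1, Irs2, Kcnk10, Lima1, Lmcd1, Nfkb1, Nr4a2, Ppp1r15a, Ppp1r3g, Rgs3, Sik1, Slc2a1, Srrm4, Tnc and Vxn. Of the 19137 symbols tested in any line, 18373 (96.0%) were in that annotation.

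Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each line was fitted on its own with 1 mean per group and 3 libraries per group. Genes were filtered with edgeR's filterByExpr by group, which left 18103 genes in the Gas line, 15980 in Gai, 15528 in Gaq and 15835 in Ga13. Libraries were scaled by TMM. Differences were tested with edgeR's robust quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. Levels are counts per 1000000 counts of the library (CPM) as mean ± SD, and fold changes are log2 with the standard error (SE) of the fit. Square roots of the common dispersion (the biological coefficient of variation) were 0.0686, 0.0911, 0.0649 and 0.0678 in the Gas, Gai, Gaq and Ga13 lines. Total counts per library ranged from 15.6 M to 42.6 M (units of 1000000 counts). Intervals of count ratios are 95% exact binomial intervals and cover counting error only. Genes with 1 to 3 counts in a group are given as count ratios.

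Within each line 6 contrasts were tested: the agonist response with empty virus, the response with Cre virus, the mean of both responses, Cre against empty virus without agonist, the same with agonist, and the difference between the responses. The biosensor sequence was reported first and left out of all counts of genes. The response score of a library was the mean, over genes called in the mean response, of log2 CPM (prior count 2) signed by the direction of that response. Its difference between viruses was tested by exact permutation of the virus label within each stimulation state, with 400 arrangements per line. The 36 fibroblast libraries were also fitted together (16749 genes) to test whether the TRAP-6 response differed between lines. Numbers of genes shared between comparisons are given beside the number expected if the lists were independent. Where shared genes are split into same and opposite direction, the expected number covers the same direction only.

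Before the data were examined, 18 gene lists and 11 cell type marker lists were fixed, 29 in all, together with the contrasts and the alternatives. The gene lists were cAMP and CREB targets, immediate early and ERK feedback genes, SRF and MRTF targets, YAP and TAZ targets, calcium and NFAT targets, NF-kB and inflammatory genes, secreted growth factors, extracellular matrix and myofibroblast genes, interferon response, p53 and DNA damage, cell cycle, unfolded protein and amino acid stress, heat shock, cholesterol synthesis, glycogen and glucose metabolism, receptors and G protein signalling, biosensor source and locus, and mitochondrially encoded genes. The marker lists covered astrocytes, microglia and macrophages, oligodendrocyte lineage, neurons, endothelium, fibroblasts, smooth muscle and pericytes, lung epithelium, mesothelium, T and B lymphocytes, and erythroid cells. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data.

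Genes were named by a rule fixed before the data were examined, which left out symbols that are Gm numbers, Rik names or pseudogenes. In the mean response it took the 10 called genes with the highest and the 6 with the lowest fold change, at a mean CPM of at least 1 and with the same direction under both viruses. From each list it took up to 4 called members with the smallest p, in the mean response and in Cre against empty. For Cre against empty it took the 6 highest and 6 lowest called genes, and for each difference between responses or lines the 6 with the smallest p. It also took the biosensor targets and the receptors of both agonists. A few genes that it took are not reported here. The left-out symbols numbered 373 among called genes of the mean response in Gas, 20 in Gai, 53 in Gaq and 99 in Ga13. They numbered 11 and 15 in Cre against empty in Gaq without and with agonist, and 1 in Ga13 with agonist.

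Whether replicate numbers pair the samples was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. In Gai every such correlation was over 0.1 (0.170 to 0.681), so counts with the replicate number as a block stand beside the Gai counts, while fold changes and p-values are without it unless stated. In the other lines only 2 pairs of groups had all 3 correlations over 0.1: unstimulated empty with stimulated empty in Ga13 (0.170, 0.179 and 0.304) and unstimulated empty with stimulated Cre in Gaq (0.115, 0.195 and 0.229). There the block was used only as an alternative. Weaker pairing may remain, since all 6 libraries of some pairs of groups correlated best with their own number. In Gaq these were stimulated Cre with each other group, and in Ga13 stimulated empty with either unstimulated group. Main counts and the score test in these lines do not use such pairing. No pair of libraries in a group was a duplicate, since their chi-square per gene lay between 2.62 and 19.3.

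The alternatives were DESeq2 in place of edgeR, RLE in place of TMM scaling, no filter on low counts, a mean CPM of at least 1, a fit of only the groups compared, the replicate block, other gene sets or a prior count of 0.5 in the score, other list tests, an adjusted p under 0.01 for overlaps, and each library left out in turn. Fits without the Gai libraries numbered 1, the comparison of Cre effects between fibroblast lines, and the score test within replicate numbers were chosen after seeing the data. The procedure was tested on simulated data with 200 changed genes per line. It recovered 86.6% (Gas), 95.5% (Gai), 92.5% (Gaq) and 97.0% (Ga13) of genes with a 2-fold change in the mean response. For a 2-fold difference between responses it recovered 76.1%, 67.2%, 64.2% and 67.2%. Among calls at an adjusted p under 0.05, the false share for Cre against empty virus with agonist was 11.0% in Gas, 4.38% in Gai, 10.6% in Gaq and 7.82% in Ga13. It was 5.56%, 5.91%, 6.67% and 7.50% for the mean response and 7.84%, 6.77%, 7.03% and 6.37% for the difference between responses. The simulated libraries were drawn independently, without the structure by replicate number found in Gai. The Gai shares may therefore not hold for the real data. Sequence reads, isoforms and imaging were not used here.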

Results

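RNA was measured in primary cells of 4 mouse lines, each carrying a BERKY3 biosensor that stays off until Cre recombinase removes a stop sequence. BERKY biosensors are luminescent proteins that detect the active, GTP-bound form of a G protein alpha subunit, and each line is named here for its subunit: Gas, Gai, Gaq or Ga13. Primary astrocytes were taken from the Gas line and primary lung fibroblasts from the other 3 lines. Cells received an adeno-associated virus with Cre (biosensor on) or an empty virus (biosensor off). They were then left in fresh medium or stimulated for 90 min. Astrocytes were given 1 µM isoproterenol, which activates beta-adrenergic receptors that couple to Gas. Fibroblasts were given 100 µM TRAP-6, a peptide that activates the thrombin receptor PAR1, encoded by F2r. The design thus asks what the agonist does to the transcriptome, what Cre with the biosensor does at rest, and whether it alters the response. Cells without the biosensor were not analysed here, so effects of Cre itself and of the biosensor are not separated. There were 16 groups of 3 libraries. Total counts per library are given in M, units of 1000000 counts. Their medians were 20.3 M in Gas, 18.4 M in Gai, 18.2 M in Gaq and 21.7 M in Ga13, and the 48 libraries ranged from 15.6 M to 42.6 M. Labels give replicate numbers only, so p-values measure the spread between samples, which may be technical.

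The biosensor transcript was near absent with empty virus and abundant with Cre in all 4 lines. In unstimulated cells given Cre it reached 24.96 ± 1.72 CPM (SD, n = 3) in Gas astrocytes. The levels in fibroblasts were 124 ± 17.6 CPM in Gai, 84.9 ± 4.91 CPM in Gaq and 116 ± 9.53 CPM in Ga13. With Cre and agonist it reached 20.5 ± 1.13, 127 ± 6.09, 90.0 ± 14.1 and 134 ± 4.24 CPM in the same order. Empty virus groups held 0.0395 to 0.720 CPM. The empty virus group of unstimulated astrocytes held only 2 counts. The median tested gene had 13.8 to 17.1 CPM in the same groups.

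**Figure D1:**
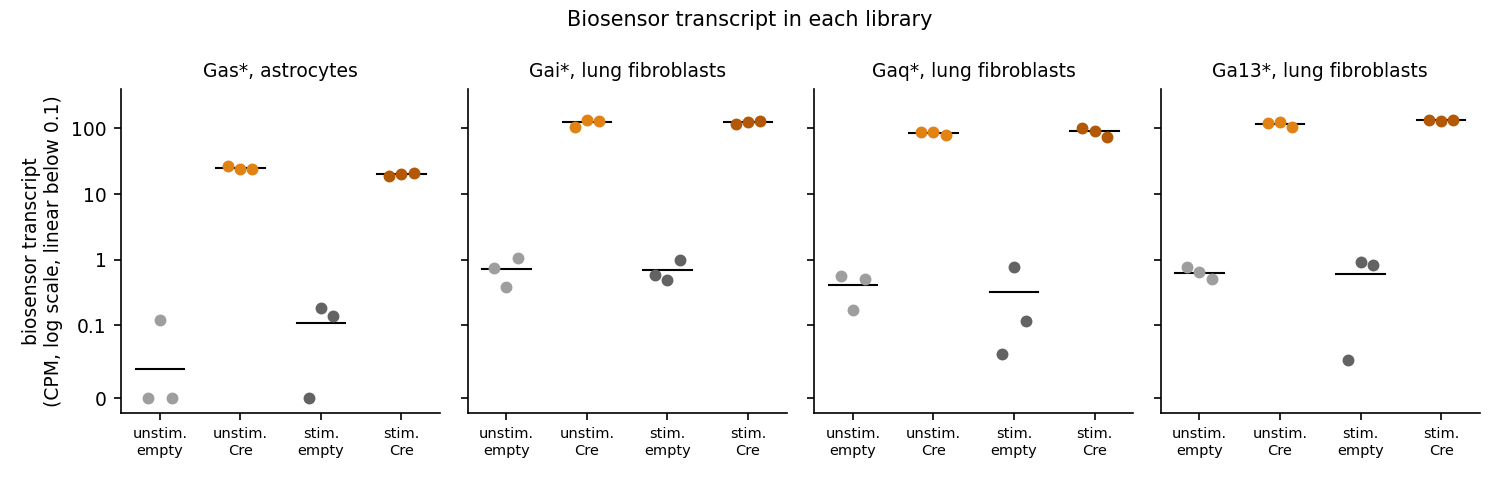
Biosensor transcript in CPM (log scale, linear below 0.1) for each library (points, 3 per group) and group mean (line), by line, stimulation and virus. Cre groups average 20.5 to 134 CPM and empty virus groups 0.0395 to 0.720 CPM.

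In astrocytes given isoproterenol Cartpt, which encodes the CART neuropeptide precursor, rose from 0.141 ± 0.0832 to 19.8 ± 2.30 CPM (SD, n = 3, empty virus), a mean log2 change over both viruses of 7.38 ± 0.17 (SE, edgeR adjusted p = 2.12e-28). Rasd1, a Ras-like inhibitor of adenylyl cyclase signalling, rose from 1.46 ± 0.508 to 103 ± 5.61 CPM (6.36 ± 0.13), and Ucp1, the uncoupling protein of brown fat, rose by 5.15 ± 0.43. The immediate early gene Arc fell from 56.6 ± 6.92 to 6.07 ± 0.738 CPM (log2 change -3.31 ± 0.07, edgeR adjusted p = 1.33e-27). Adrb1, the beta-1 receptor of the agonist, fell from 62.9 ± 8.92 to 27.0 ± 2.87 CPM (-1.33 ± 0.09, edgeR adjusted p = 1.35e-07).

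The mean response of both viruses included 2127 rising and 2084 falling genes of 18103 tested (23.3%), of which 453 and 145 changed at least 2-fold. With empty virus alone 1435 rose and 1218 fell, and with Cre 1360 and 1223. Of these, 1922 genes were called the same way under both viruses with none called opposite (190 expected by chance). Among the largest rises were also Ghsr, the ghrelin receptor, with 2 counts unstimulated and 640 stimulated over 6 libraries each, a ratio of 323 (95% interval 89.0 to 2672). C2cd4b had 2 and 354 counts (ratio 179, interval 49.1 to 1480.5). The hormone precursor Trh rose by 6.06 ± 0.27, Pax9 by 5.56 ± 0.23, Klf14 by 5.28 ± 0.41 and Epn3 by 5.08 ± 0.25. C2cd4b, Rasd1, Pax9 and Epn3 overlap other annotated genes, which leaves their counts uncertain. The largest falls after Arc were in Rgs16 (-2.93 ± 0.16), which speeds the shut-off of G proteins, Sox7 (-2.62 ± 0.12), the transcription factor gene Egr3 (-2.19 ± 0.10) and the growth factor gene Pdgfb (-2.16 ± 0.12).

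Of 28 cAMP and CREB targets, 26 rose and 2 fell (26 and 2 adjusted over the list alone), with a median log2 change of 2.08 (camera adjusted p = 2.22e-28, adjusted p = 0.0483 with an estimated correlation). Fos rose by 2.81 ± 0.05, the GTPase activator Rgs2 by 2.12 ± 0.04 and the insulin signalling adaptor Irs2 by 1.55 ± 0.04. Immediate early and ERK feedback genes went both ways, with 12 rising and 17 falling of 31 (12 and 17 adjusted over the list alone), a median of -0.21, a mean of 0.04 and camera adjusted p = 0.361. SRF and MRTF targets fell, 20 of 30 against 2 that rose (22 and 4 adjusted over the list alone; camera adjusted p = 3.97e-06, adjusted p = 0.341 with an estimated correlation). Among them Srf itself went from 149 ± 10.5 to 77.9 ± 3.92 CPM (-1.01 ± 0.05) and the matrix protein gene Ccn1 fell by 0.78 on the log2 scale, while the smooth muscle calponin Cnn1 rose by 0.94 ± 0.04. Cholesterol synthesis genes fell, 17 of 22 (17 adjusted over the list alone; camera adjusted p = 3.97e-06, adjusted p = 0.341 with an estimated correlation), and mevalonate kinase Mvk alone rose (1.03 ± 0.05).

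NF-kB and inflammatory genes rose as a list, with 12 up and 6 down of 26 (12 and 7 adjusted over the list alone; camera adjusted p = 0.0273, adjusted p = 0.341 with an estimated correlation). Il6 rose by 3.44 ± 0.30 from a low level of 0.163 ± 0.101 CPM, Ier3 by 2.49 ± 0.06 and Nfkb1 by 0.91 ± 0.05, while Irf1 changed by -1.50 ± 0.07. Glycogen and glucose genes rose, 9 up and 2 down of 22 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0273, adjusted p = 0.231 with an estimated correlation). They included Ppp1r3g, which targets a phosphatase to glycogen (3.39 ± 0.20), and the glucose transporter Slc2a1 (0.73 ± 0.04). Of 34 cell cycle genes 9 fell and none rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.0216, adjusted p = 0.341 with an estimated correlation), among them Aurka (-0.49 ± 0.10) and Cenpe (-0.45 ± 0.06). Neuron markers rose, 3 of 11 (3 adjusted over the list alone; camera adjusted p = 0.0273, adjusted p = 0.341 with an estimated correlation). Growth factor genes split, 10 up and 7 down of 25 (10 and 7 adjusted over the list alone; camera adjusted p = 0.206), with Gdnf at 2.31 ± 0.12 and Hbegf at -1.36 ± 0.04.

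None of the remaining lists passed camera in the astrocyte response, at adjusted p of 0.0798 to 0.74. Rising and falling genes numbered 4 and 8 of 22 YAP and TAZ targets (5 and 8 adjusted over the list alone; median 0.00, mean -0.11), 7 and 4 of 15 calcium and NFAT targets (7 and 5), and 8 and 3 of 27 matrix genes (8 and 3). They were 4 and 3 of 34 interferon genes (3 and 3), 6 and 6 of 28 p53 targets (7 and 6; median -0.01, mean 0.11), 5 and 3 of 24 unfolded protein genes (5 and 3) and 3 and 1 of 13 heat shock genes (3 and 1). Among 50 receptor and G protein genes 11 rose and 8 fell (11 and 8), including F2rl1 (1.08 ± 0.09) and Rgs3 (-0.71 ± 0.07), and among 5 genes of the biosensor source and locus 2 fell (2). For markers the numbers were 5 and 1 of 13 for astrocytes (6 and 2), 4 and 1 of 18 for microglia (5 and 1), 3 and 1 of 11 for oligodendrocytes (3 and 1), and 3 and 1 of 11 for fibroblasts (3 and 1). They were 1 and 2 of 8 for smooth muscle (1 and 3; median -0.05, mean 0.01), 2 and 0 of 5 for lung epithelium (2 and 0) and 0 and 0 of 8 for endothelium (0 and 0). Of the mesothelial markers 1 gene was measured, and of lymphocyte, erythroid and mitochondrially encoded genes 0. In each fibroblast line no more than 1 lymphocyte, 1 erythroid and 2 neuron markers were measured, and none of these was called.

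**Figure D2:**
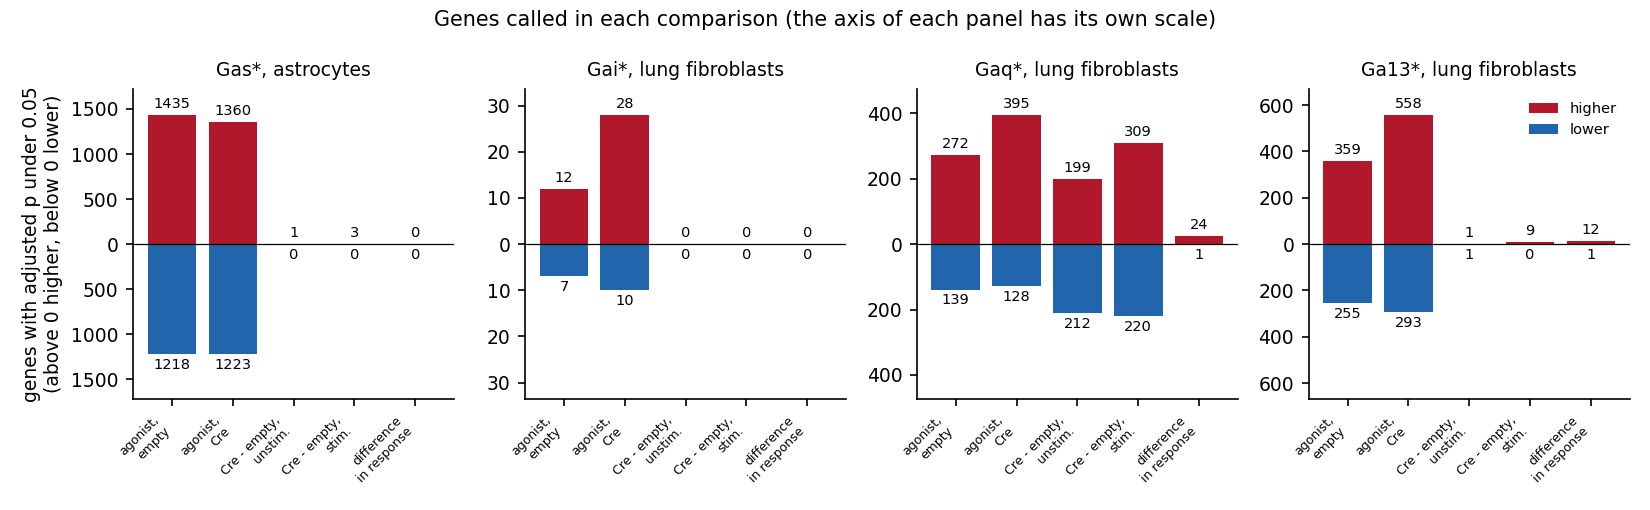
Number of genes with adjusted p under 0.05 that were higher (above 0) or lower (below 0) in each comparison, by line, each panel with its own scale. Cre against empty virus gives 1 and 3 genes in Gas, 0 and 0 in Gai, 411 and 529 in Gaq, and 2 and 9 in Ga13.

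Cre changed few astrocyte genes. Pdgfra, the growth factor receptor of oligodendrocyte precursors, rose with Cre from 103 ± 5.04 to 135 ± 4.44 CPM (SD, n = 3) without agonist (0.39 ± 0.05, edgeR adjusted p = 0.000222), the only gene called. With agonist Pdgfra rose from 116 ± 2.26 to 143 ± 6.18 CPM (0.30 ± 0.05, edgeR adjusted p = 0.0297). The oligodendrocyte transcription factor gene Sox10 rose by 0.52 ± 0.10 (edgeR adjusted p = 0.0297) and Vxn by 0.35 ± 0.07 (edgeR adjusted p = 0.0363). The unstimulated count was 2 without unstimulated Cre replicate 1 and 4 without replicate 2. The stimulated count fell to 0 when any of stimulated empty replicates 1, 2 and 3 or stimulated Cre replicates 2 and 3 was left out, and Vxn was also lost without stimulated Cre replicate 1 (edgeR adjusted p = 0.110). Of 11 oligodendrocyte markers, 1 rose without agonist (5 adjusted over the list alone; camera adjusted p = 8.2e-06, adjusted p = 0.28 with an estimated correlation) and 2 with agonist (3 adjusted over the list alone; camera adjusted p = 1.86e-07, adjusted p = 0.129 with an estimated correlation). Interferon genes were lower as a list in both states, with 0 of 34 called (0 rising and 3 falling, then 0, adjusted over the list alone). Their median log2 changes were -0.19 and -0.17 (camera adjusted p = 1.29e-06 and 8.07e-07, adjusted p = 0.652 and 0.849 with an estimated correlation). Immediate early genes were higher without agonist (median 0.07, camera adjusted p = 0.0163, adjusted p = 0.652 with an estimated correlation), and cell cycle genes with agonist (median 0.08, camera adjusted p = 6.51e-05, adjusted p = 0.36 with an estimated correlation). The isoproterenol response did not differ between viruses for any gene by edgeR or by DESeq2 (0 genes each, 631 at an unadjusted p under 0.05).

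In Gai fibroblasts given TRAP-6 the serine protease gene Tmprss7 rose from 2.43 ± 0.631 to 6.40 ± 1.46 CPM (SD, n = 3, empty virus; mean log2 change 1.55 ± 0.20, edgeR adjusted p = 0.000678), and Arc rose by 0.52 ± 0.05 (edgeR adjusted p = 1.59e-05). Smad6, an inhibitor of BMP signalling, fell from 29.9 ± 5.62 to 15.2 ± 0.375 CPM (-0.92 ± 0.10, edgeR adjusted p = 0.000107), the planar polarity gene Prickle1 by 1.05 and the ERK feedback inhibitor Spry4 by 0.60. Over both viruses 117 genes rose and 62 fell of 15980 tested, 26 and 4 of them at least 2-fold. With the replicate number as a block 797 genes were called, 462 rising and 335 falling. With empty virus 12 rose and 7 fell, and with Cre 28 and 10 (254 and 355 called with the block), 18 of them shared in direction (0.0254 expected by chance). The empty virus count of 19 was 12 without stimulated empty replicate 1, and 10 and 11 without unstimulated empty replicates 2 and 3. The Cre count of 38 was 17 without unstimulated Cre replicate 1, 15 without replicate 3, and 17 and 18 without stimulated Cre replicates 2 and 3.

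Of 24 cAMP and CREB targets 4 rose in Gai (8 rising and 2 falling adjusted over the list alone; camera adjusted p = 4.22e-06, adjusted p = 0.483 with an estimated correlation), including Nr4a2 (0.79 ± 0.11, from 87.6 ± 16.5 to 157 ± 14.3 CPM), Fosb (0.58 ± 0.09) and Nr4a3 (0.38 ± 0.05). Of 31 immediate early genes 5 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.000203, adjusted p = 0.561 with an estimated correlation), with Myc at 0.33 ± 0.05 and Mcl1 at 0.28 ± 0.05. Cholesterol synthesis genes fell, 2 of 22 (4 adjusted over the list alone; camera adjusted p = 8.99e-07, adjusted p = 0.483 with an estimated correlation), namely Insig1 (-0.29 ± 0.05) and Stard4 (-0.28 ± 0.05). Interferon genes rose as a list with 0 of 33 called (10 adjusted over the list alone; median 0.25, camera adjusted p = 4.87e-09, adjusted p = 0.483 with an estimated correlation). SRF targets, unfolded protein genes with Chac1 (0.48 ± 0.08), heat shock genes and mesothelial markers also passed upward (camera adjusted p = 0.000287, 0.00103, 0.0313 and 0.031). Endothelial markers passed downward (camera adjusted p = 0.0455). None of these 5 held with an estimated correlation (adjusted p = 0.532, 0.325, 0.325, 0.483 and 0.483), and with the block endothelial markers gave 0.0828 and fibroblast markers 0.0343. Outside these lists Gdnf rose by 0.32 ± 0.05 and hexokinase 2 (Hk2) fell by 0.23 on the log2 scale. The rule also named BC016579, Apol8, Srrm4, Lce1l, Frat2, H1f1, Etaa1, Hspa5 and Amotl2, whose calls were lost in 1 to 9 of 12 fits that left out a library.

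In Gaq and Ga13 fibroblasts TRAP-6 raised immediate early genes and SRF and MRTF targets. Nfatc2, a calcium-activated transcription factor, rose from 1.62 ± 0.607 to 3.87 ± 0.856 CPM in Gaq (SD, n = 3, empty virus; mean log2 change 2.15 ± 0.26, edgeR adjusted p = 8.87e-06) and from 0.893 ± 0.301 to 4.04 ± 0.789 CPM in Ga13 (2.17 ± 0.23, edgeR adjusted p = 6.29e-08). Serpinb2, an inhibitor of plasminogen activators, rose by 1.30 ± 0.06 in Ga13, and the deubiquitinase gene Usp2, which overlaps Gm39325 and has an uncertain count, by 1.34 ± 0.05 and 1.34 ± 0.06. The Notch target gene Hes1 fell from 21.3 ± 1.72 to 10.4 ± 0.847 CPM in Ga13 (-1.02 ± 0.07), Prickle1 fell by 1.09 in Ga13, and Ier5l by 0.97 in Gaq. The mean response held 587 rising and 284 falling of 15528 genes in Gaq and 742 and 585 of 15835 in Ga13, of which 43 and 7, and 60 and 14, changed at least 2-fold. With empty virus 272 rose and 139 fell in Gaq and 359 and 255 in Ga13. With Cre 395 rose and 128 fell in Gaq and 558 and 293 in Ga13. The Gaq counts of 411 and 523 were 261 without stimulated empty replicate 1 and 333 without unstimulated Cre replicate 1.

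Of 25 cAMP and CREB targets, 17 rose in Gaq and 18 in Ga13 with none falling (18 and 0 in Gaq, 19 and 1 in Ga13 adjusted over the list alone; camera adjusted p = 3.42e-27 and 1.09e-19, adjusted p = 0.0086 and 0.0613 with an estimated correlation). The phosphatase gene Dusp1 rose by 0.60 ± 0.04 in Gaq and 0.77 ± 0.03 in Ga13, and Rgs2 by 1.19 ± 0.10 and 1.05 ± 0.13. Immediate early genes rose, 20 up and 4 down of 31 in Gaq and 22 and 4 in Ga13 (21 and 5, and 23 and 5, adjusted over the list alone; camera adjusted p = 1.24e-11 and 3.99e-16, adjusted p = 0.0086 and 0.033 with an estimated correlation). Atf3 rose by 0.72 ± 0.04 and 0.80 ± 0.04, and Myc by 0.50 ± 0.04 and 0.64 ± 0.03. SRF and MRTF targets rose, 15 of 30 in Gaq and 24 in Ga13 against 1 fall there (22, and 28 and 1, adjusted over the list alone; camera adjusted p = 6.27e-14 and 4.51e-22, adjusted p = 0.0434 and 0.033 with an estimated correlation). The focal adhesion gene Vcl, which overlaps Ap3m1, rose by 0.35 ± 0.03 and 0.41 ± 0.02, and Pdlim5 by 0.29 ± 0.03 and 0.39 ± 0.03. YAP and TAZ targets rose, 9 up and 2 down of 23 in each line (12 and 4, and 11 and 3, adjusted over the list alone; camera adjusted p = 0.0002 and 0.000275, adjusted p = 0.0434 and 0.033 with an estimated correlation), led by Amotl2 (0.54 ± 0.03 in both). Calcium and NFAT targets also rose, 7 up and 4 down of 14 in Gaq and 6 and 2 in Ga13 (8 and 4, and 9 and 3, adjusted over the list alone; camera adjusted p = 0.00545 and 0.000467, adjusted p = 0.244 and 0.23 with an estimated correlation). The prostaglandin synthase gene Ptgs2 rose from 2002 ± 35.9 to 2742 ± 99.4 CPM in Gaq (0.46 ± 0.03) and by 0.59 ± 0.03 in Ga13.

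Growth factor genes rose as a list, 6 up and 2 down of 26 in Gaq and 8 and 3 in Ga13 (7 and 3, and 9 and 3, adjusted over the list alone; camera adjusted p = 0.00315 and 0.000467, adjusted p = 0.163 and 0.0693 with an estimated correlation). Gdnf rose by 0.76 ± 0.04 in Gaq and 0.76 ± 0.05 in Ga13, Bdnf by 0.39 ± 0.04 and 0.45 ± 0.03, and Lif changed by -0.35 ± 0.04 in Gaq. Matrix genes rose, 6 of 28 in each line (8 and 9 adjusted over the list alone; camera adjusted p = 4.5e-05 and 4.2e-05, adjusted p = 0.244 and 0.0403 with an estimated correlation), with tenascin C (Tnc) at 0.34 ± 0.03 and 0.34 ± 0.02. Heat shock genes rose, 3 and 5 of 13 (4 and 5 adjusted over the list alone; camera adjusted p = 0.000722 and 3.7e-05, adjusted p = 0.244 and 0.0693 with an estimated correlation), with Dnajb1 at 0.28 ± 0.04 and 0.35 ± 0.03. In Ga13 interferon genes were lower as a list with 0 of 33 called (0 adjusted over the list alone; median -0.30, camera adjusted p = 0.000601, adjusted p = 0.689 with an estimated correlation). Astrocyte markers were higher in Ga13 with 1 of 9 called (2 adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.334 with an estimated correlation). NF-kB genes had a median of -0.01 and a mean of 0.06 in Gaq and a median of -0.05 and a mean of 0.03 in Ga13 (camera adjusted p = 0.832 and 0.611). F2r, the receptor of TRAP-6, stood at 390 to 474 CPM in the Gai, Gaq and Ga13 groups and did not respond to TRAP-6 (edgeR adjusted p = 0.814, 0.578 and 0.761).

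**Figure D3:**
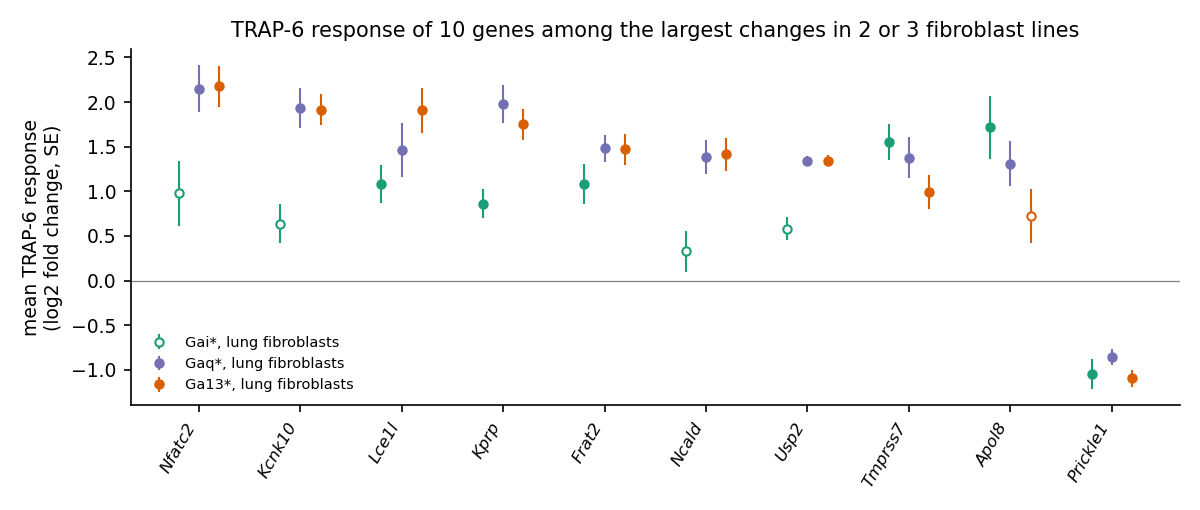
Mean TRAP-6 response (log2 fold change over both viruses, bars SE, filled points adjusted p under 0.05) of 10 genes that are among the largest called changes in at least 2 fibroblast lines. Frat2 rises by 1.08 in Gai, 1.48 in Gaq and 1.47 in Ga13, and Prickle1 falls in all of them. These fits have no replicate block. With it Nfatc2, Kcnk10 and Usp2 are also called in Gai (adjusted p = 0.000418, 0.00328 and 0.000167).

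The responses of the fibroblast lines shared many genes. Gaq and Ga13 called 602 genes in the same direction and 1 in opposite directions (38.6 expected by chance), Gai and Gaq 125 and 0 (5.38 expected), and Gai and Ga13 136 and 0 (7.61 expected). The astrocyte response to isoproterenol overlapped less evenly, with 443 genes in the same direction and 252 opposite to Ga13 (160 expected). It shared 297 and 174 to Gaq (103 expected), and 52 and 39 to Gai (19.1 expected). These expected numbers are for genes in the same direction only. No such number was computed for opposite genes, so they are not set against chance here. Tested directly in a joint fit of 36 libraries, 23 genes responded differently in Gaq than in Gai (22 higher, 1 lower) and 53 in Ga13 than in Gai (48 higher, 5 lower). None differed between Ga13 and Gaq by edgeR or by DESeq2 (851 genes at an unadjusted p under 0.05). With the replicate number as a block these 3 counts were 161, 288 and 7. The kinase gene Sgk1 rose by 0.17 in Gai, 0.52 in Gaq and 0.54 in Ga13, which was 0.34 ± 0.05 above Gai for Gaq (edgeR adjusted p = 0.000103) and 0.36 ± 0.05 for Ga13 (edgeR adjusted p = 2.54e-05). Tnfaip6, which encodes a hyaluronan-binding protein, rose by 0.77 ± 0.12 more in Gaq (edgeR adjusted p = 0.000443), and Gdnf by 0.44 ± 0.07 more in Gaq and in Ga13. The zinc finger gene Hivep1 was at -0.05 in Gai, 0.34 in Gaq and 0.38 in Ga13 (0.40 ± 0.06 and 0.43 ± 0.06 higher than in Gai), and the repressor Zfp503 fell more in Gaq (-0.43 ± 0.07, edgeR adjusted p = 0.00101). Sgk1 and Zfp503 overlap other annotated genes, which leaves their counts uncertain.

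These counts between lines moved with single libraries. The Gaq against Gai count of 23 was 39 without Gai stimulated empty replicate 1, 49 without stimulated Cre 1, 5 without unstimulated empty 2 and 6 without stimulated Cre 2. It was 12 without unstimulated empty 3, 6 without unstimulated Cre 3, 6 without stimulated empty 3 and 14 without stimulated Cre 3. It was also 13 without Gaq unstimulated Cre 1, 10 without stimulated Cre 1 and 15 without unstimulated empty 2. It was 7 without stimulated empty 2, 7 without stimulated Cre 2, 12 without unstimulated empty 3, 7 without unstimulated Cre 3 and 15 without stimulated empty 3. The Ga13 against Gai count of 53 was 104 without Gai stimulated Cre replicate 1, 33 without unstimulated empty 2 and 35 without unstimulated Cre 3. Sgk1, Gdnf, Tnfaip6, Hivep1 and Zfp503 stayed called in every fit that left out a library.

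Cre changed resting gene expression widely in Gaq fibroblasts. The interleukin 33 receptor Il1rl1 fell from 78.5 ± 6.26 to 38.3 ± 0.849 CPM without agonist (SD, n = 3; -1.04 ± 0.07, edgeR adjusted p = 1.47e-12). The steroid-metabolising Akr1c18 fell from 16.6 ± 1.45 to 7.62 ± 1.01 CPM (-1.12 ± 0.13, edgeR adjusted p = 9.89e-07) and haptoglobin (Hp) from 9.21 ± 0.281 to 4.46 ± 0.349 CPM (-1.05 ± 0.15). Igfbp3, which binds insulin-like growth factors, rose from 329 ± 53.1 to 636 ± 35.1 CPM (0.95 ± 0.12, edgeR adjusted p = 0.00279). Type III collagen (Col3a1) rose from 6503 ± 126 to 9034 ± 519 CPM (0.47 ± 0.06, edgeR adjusted p = 0.000224). With agonist the lymphatic growth factor gene Vegfd rose from 28.1 ± 1.97 to 58.4 ± 10.7 CPM (1.06 ± 0.14) and the integrin gene Itgb3 fell from 78.5 ± 6.01 to 41.7 ± 6.53 CPM (-0.92 ± 0.11). Without agonist 199 genes were higher and 212 lower with Cre, and with agonist 309 and 220 (752 and 944 called in all with the replicate number as a block). Of these, 207 were called in the same direction in both states and 3 in opposite directions (6.96 expected by chance). The count of 411 without agonist was 262 without unstimulated Cre replicate 1 and 272 without replicate 2. The count of 529 with agonist was 296 without stimulated empty replicate 1, and 303 and 283 without stimulated Cre replicates 1 and 2. In simulated data 10.6% of the calls of Cre against empty virus with agonist in Gaq were false.

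Growth factor genes were lower with Cre in unstimulated Gaq cells, 9 of 26 and none higher (12 lower and 2 higher adjusted over the list alone; camera adjusted p = 1.71e-07, adjusted p = 0.0569 with an estimated correlation). Lif changed by -0.42 ± 0.05, Vegfa by -0.27 ± 0.04 and Hgf by -0.43 ± 0.08. With agonist 5 were lower and 1 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.0347, adjusted p = 0.285 with an estimated correlation). Of 25 cAMP and CREB targets 6 were lower in each state (10 adjusted over the list alone in each; camera adjusted p = 5.92e-06 and 0.000115, adjusted p = 0.184 and 0.285 with an estimated correlation), among them Sik1 without agonist (-0.26 ± 0.05) and Rgs2 with agonist (-0.65 ± 0.13). Calcium and NFAT targets were lower, 5 of 14 in each state (6 lower with 1 and 2 higher adjusted over the list alone; camera adjusted p = 0.000184 and 0.048, adjusted p = 0.183 and 0.426 with an estimated correlation). Rgs16 changed by -0.58 ± 0.06 and -0.59 ± 0.06, and Ptgs2 by -0.29 ± 0.05 and -0.28 ± 0.05. Immediate early genes and NF-kB genes were lower without agonist (3 of 31 and 3 of 24 called, against 0 and 1 higher; 7 and 7 lower and 0 and 2 higher adjusted over the list alone; camera adjusted p = 0.00232 and 0.0048, adjusted p = 0.17 and 0.254 with an estimated correlation).

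The p53 targets were higher with Cre in Gaq, 5 of 28 in each state against 1 and 0 lower (7 and 8 higher with 1 and 2 lower adjusted over the list alone; camera adjusted p = 0.000462 and 0.0034, adjusted p = 0.0651 and 0.169 with an estimated correlation). Trp53inp1 changed by 0.43 ± 0.05 and 0.32 ± 0.05, and Eda2r by 0.34 ± 0.06 in each state. Fibroblast markers were higher, 3 and 6 of 12 (5 and 10 higher with 1 and 0 lower adjusted over the list alone; camera adjusted p = 0.000462 and 6.71e-08, adjusted p = 0.226 and 0.169 with an estimated correlation), and mesothelial markers, 1 of 6 in each state (2 and 5 adjusted over the list alone; camera adjusted p = 0.00154 and 0.000115, adjusted p = 0.226 and 0.285 with an estimated correlation). Matrix genes were higher with agonist, 7 up and 3 down of 28 (10 and 6 adjusted over the list alone; camera adjusted p = 0.0466, adjusted p = 0.486 with an estimated correlation), with Col1a1 at 0.25 ± 0.04 while thrombospondin 1 (Thbs1) changed by -0.25 ± 0.03. SRF targets were higher with agonist, 6 of 30 (12 up and 2 down adjusted over the list alone; camera adjusted p = 0.000212, adjusted p = 0.301 with an estimated correlation), with Lima1 at 0.29 ± 0.05. Interferon genes were higher with 1 of 33 called in each state (1 and 3 adjusted over the list alone; median 0.55 and 0.33, camera adjusted p = 5.39e-10 and 7.39e-05, adjusted p = 0.372 and 0.486 with an estimated correlation). Astrocyte markers passed without agonist (2 up and 1 down of 9; 3 and 1 adjusted over the list alone; camera adjusted p = 0.00572, adjusted p = 0.11 with an estimated correlation). Among receptors the alpha-1B adrenergic receptor Adra1b rose by 0.84 ± 0.16 with agonist. F2r fell by 0.14 at rest (edgeR adjusted p = 0.0466), a call lost without unstimulated empty replicate 1 or unstimulated Cre replicates 1, 2 or 3 (edgeR adjusted p = 0.227, 0.134, 0.0994 and 0.224).

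**Figure D4:**
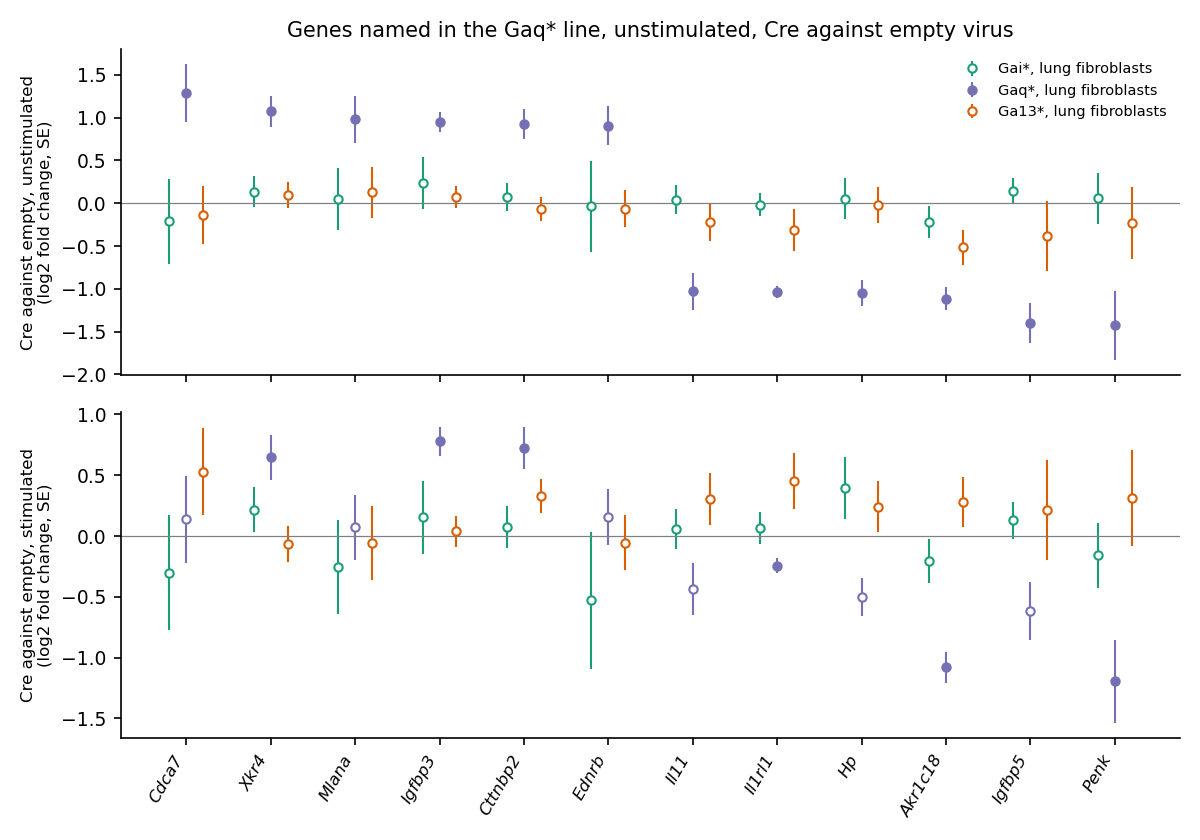
Cre against empty virus (log2 fold change, bars SE, filled points adjusted p under 0.05) without and with agonist for the genes with the largest called changes in unstimulated Gaq fibroblasts, in the 3 fibroblast lines. Il1rl1 falls by 1.04 without agonist in Gaq, and no plotted gene is called in Gai or Ga13 in these fits, while Igfbp3 is called in Gai without agonist with the replicate number as a block (0.25, adjusted p = 0.0363).

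In Ga13 fibroblasts Cre raised the non-coding transcript of the Rosa26 locus, Gt(ROSA)26Sor, where many transgenes are placed. It went from 3.41 ± 0.529 to 6.93 ± 1.44 CPM without agonist (SD, n = 3; 1.04 ± 0.18, edgeR adjusted p = 0.0221) and from 3.37 ± 0.703 to 8.13 ± 1.36 CPM with agonist (1.25 ± 0.19, edgeR adjusted p = 0.00069). The transcript overlaps Thumpd3 and its count is uncertain, and the call without agonist was lost without unstimulated Cre replicates 1 or 2 or unstimulated empty replicates 2 or 3 (edgeR adjusted p = 0.114, 0.319, 0.284 and 0.322). Without agonist the signalling regulator Lmcd1 was the other gene called (-0.25 ± 0.05, edgeR adjusted p = 0.0477), and it was lost in 5 of the 6 fits that left out a library compared. The count of 2 was 1 without unstimulated empty replicate 1, 2 or 3, and 0 without unstimulated Cre replicate 1 or 2. For this comparison DESeq2 called 2 higher and 5 lower, fits without a filter on low counts 18 and 15, and the replicate block 12 and 21. With agonist 9 genes rose, including the cornified envelope protein gene Ivl (0.48 ± 0.07, edgeR adjusted p = 0.0021) and the kinase gene Lrrk2 (0.35 ± 0.05, edgeR adjusted p = 0.000487). The count of 9 was 3 without stimulated empty replicate 1, 5 and 4 without stimulated Cre replicates 1 and 2, and 15 without replicate 3. DESeq2 gave 26 higher and 4 lower, fits without a filter on low counts 49 and 14, and the replicate block 93 and 19. Interferon genes were higher as a list without agonist, with 0 of 33 called (0 adjusted over the list alone; median 0.66, camera adjusted p = 1.88e-14, adjusted p = 0.432 with an estimated correlation). None of the other lists that passed between the viruses in Ga13 held with an estimated correlation (adjusted p = 0.23 to 0.624).

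In Gai fibroblasts Cre changed no gene by edgeR in either state (407 and 348 genes at an unadjusted p under 0.05; 1 and 2 genes by DESeq2). With the replicate number as a block 11 and 9 genes were called, and the stimulated count of 0 was 3 without stimulated empty replicate 1. Chosen after their values were seen among the blocked calls, keratin 18 (Krt18) rose by 0.68 without agonist (edgeR adjusted p = 0.000193) and 0.89 with agonist (edgeR adjusted p = 4.73e-07), and Gt(ROSA)26Sor by 0.67 and 0.79 (edgeR adjusted p = 0.0363 and 0.0112). Cell cycle genes were higher with Cre as a list, with 0 of 34 called (1 and 4 adjusted over the list alone; median 0.21 in each state, camera adjusted p = 1.55e-09 and 8.69e-15, adjusted p = 0.0162 and 0.00368 with an estimated correlation). Mesothelial markers were higher in both states (2 of 6 adjusted over the list alone in each; camera adjusted p = 8.84e-05 and 9.79e-05, adjusted p = 0.197 and 0.321 with an estimated correlation), and so were interferon, cholesterol synthesis, NF-kB and lung epithelial lists in both states and smooth muscle markers without agonist (camera adjusted p = 4.54e-13 to 0.0492, adjusted p = 0.197 to 0.982 with an estimated correlation). Macrophage markers were lower with agonist (camera adjusted p = 0.00188, adjusted p = 0.747 with an estimated correlation).

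TRAP-6 responses differed between the viruses for 25 genes in Gaq and 13 in Ga13 by edgeR. The counts depended on the processing, with 40 and 60 by DESeq2, 67 and 86 without a filter on low counts, and 91 and 138 with the replicate number as a block. In Gaq the log2 response of Il1rl1 was 0.15 with empty virus, which did not pass (edgeR adjusted p = 0.253), and 0.94 with Cre, a difference of 0.79 ± 0.09 (edgeR adjusted p = 8.22e-06). Lmcd1 rose by 0.24 with empty virus and 0.97 with Cre (difference 0.73 ± 0.09, edgeR adjusted p = 7.41e-05). The nuclear RNA Neat1 fell by 0.92 with empty virus and was at 0.22 with Cre, which did not pass (difference 1.15 ± 0.11, edgeR adjusted p = 0.000359), and Serpinb2 rose by 0.74 and 1.34 (difference 0.60 ± 0.10, edgeR adjusted p = 0.00468). In Ga13, Lrrk2 rose by 0.31 with empty virus and 0.77 with Cre (difference 0.45 ± 0.07, edgeR adjusted p = 0.00694), while the response of the stress phosphatase subunit Ppp1r15a was smaller with Cre (-0.48 ± 0.08, edgeR adjusted p = 0.0104, and 0.0507 without stimulated empty replicate 3). The difference (Cre minus empty) was positive for 24 genes and negative for 1 in Gaq, and for 12 and 1 in Ga13. The response was larger in size with Cre for 19 of the 25 Gaq genes and 10 of the 13 Ga13 genes, and smaller for 6 and 3. In sign, 24 of the 25 Gaq differences went in the same direction in Ga13, but 16 of 25 in Gai and 8 of the 22 measured in Gas. Their median size was 0.54 in Gaq, and the median signed by the Gaq direction was 0.28 in Ga13 and 0.06 in Gai. Of the 13 Ga13 differences, 13 went the same way in Gaq, and 7 each in Gai and Gas. Lmcd1 and the thrombin-binding receptor Thbd, chosen after its values were seen, were called in both Gaq and Ga13 (0.0212 expected by chance). The Lmcd1 call in Ga13 was lost in 9 of 12 fits that left out a library (edgeR adjusted p up to 0.176), and the Thbd calls in 8 of 12 in Gaq and 7 of 12 in Ga13 (edgeR adjusted p up to 0.183 and 0.168).

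The Gaq count of 25 was 11 without unstimulated empty replicate 1, 7 without unstimulated Cre 1, 8 without stimulated empty 1 and 15 without stimulated Cre 1. It was 9 without stimulated Cre 2, 7 without unstimulated Cre 3 and 43 without stimulated Cre 3. The Ga13 count of 13 was 4 without unstimulated empty replicate 1, 3 without unstimulated Cre 1, 3 without stimulated empty 1, 5 without stimulated Cre 1 and 3 without unstimulated Cre 2. It was 5 without stimulated empty 2, 5 without stimulated Cre 2, 4 without unstimulated empty 3, 3 without stimulated empty 3 and 22 without stimulated Cre 3. In Gai no response differed by edgeR or DESeq2 (345 genes at an unadjusted p under 0.05). As lists, SRF targets had positive differences in Gaq (median 0.11, camera adjusted p = 2.33e-05, adjusted p = 0.694 with an estimated correlation), and so did growth factor genes in Gaq and Ga13 (0 and 1 of 26 called, 2 up in Gaq and 8 up and 2 down in Ga13 adjusted over the list alone). Camera gave adjusted p = 0.0485 and 0.000953 for the latter (adjusted p = 0.694 and 0.2 with an estimated correlation). Unfolded protein genes had negative differences in Ga13 (camera adjusted p = 0.00294, adjusted p = 0.104 with an estimated correlation), and interferon genes negative ones in Ga13 and positive ones in Gai (camera adjusted p = 3.36e-05 and 0.00382, adjusted p = 0.784 and 0.968 with an estimated correlation).

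The response score, a mean over all agonist-responsive genes, gave no difference between viruses that passed the exact permutation test. Each line's score covers its own called genes (4211 in Gas, 179 in Gai, 871 in Gaq and 1327 in Ga13). Scores therefore do not compare the size of the response between lines. The astrocyte response to isoproterenol was 0.551 with empty virus and 0.541 with Cre (98.3% of it; difference -0.00920, exact permutation p = 0.645, adjusted 0.84, n = 3 per group). The TRAP-6 response was 0.564 and 0.629 in Gai (111%; difference 0.0644, exact permutation p = 0.34, adjusted 0.68) and 0.369 and 0.403 in Gaq (109%; 0.0337, exact permutation p = 0.215, adjusted 0.68). In Ga13 it was 0.357 and 0.353 (98.9%; -0.00396, exact permutation p = 0.84, adjusted 0.84). The smallest p that 400 arrangements allow is 0.005. These arrangements do not use the pairing of Gai libraries by replicate number. Within Gai replicates 1, 2 and 3 the difference was 0.0788, 0.0484 and 0.0659, positive in 3 of 3 with an SD of 0.0153. Exchanging the signs of these 3 differences allows 8 arrangements and no exact p under 0.25, so a difference paired in this way stays open. Exchanging virus labels within each replicate number and state gave an exact permutation p = 0.375 (64 arrangements). Both tests were chosen after seeing the data. The Gas difference changed sign without unstimulated empty replicate 1 or 3 or unstimulated Cre replicate 2, up to 0.00801. The Ga13 difference did so without unstimulated empty 1, stimulated Cre 1, unstimulated Cre 3 or stimulated empty 3, up to 0.00606. With only the rising genes in the score, the Gaq difference was 0.0793 (exact permutation p = 0.01).

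**Figure D5:**
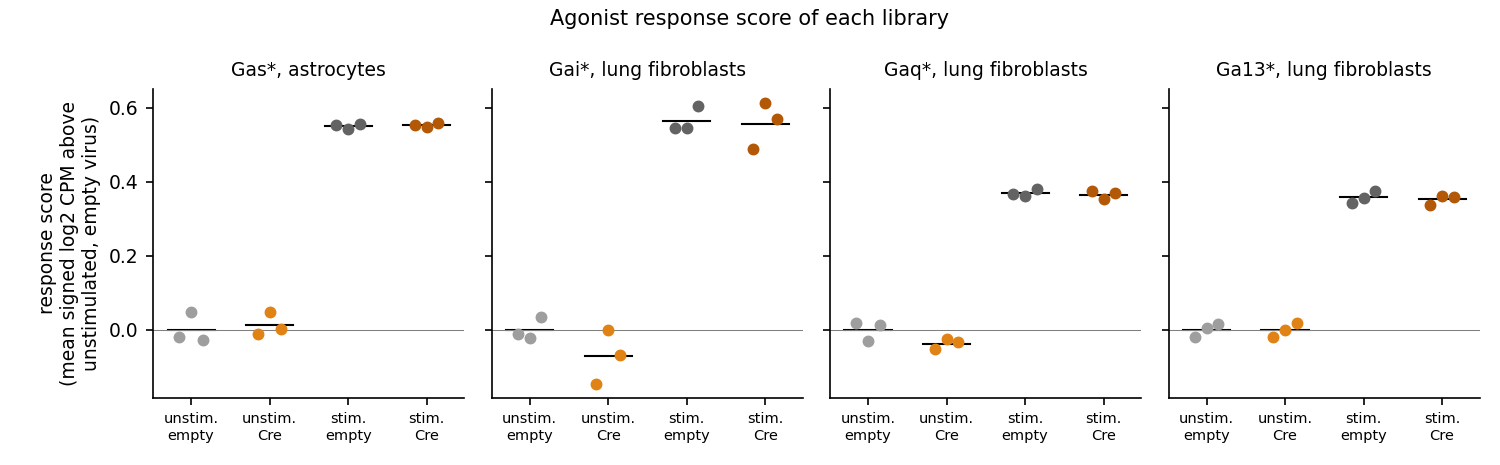
Agonist response score of each library (points; line, group mean), as mean signed log2 CPM above the unstimulated empty virus mean, by line, stimulation and virus. Stimulated minus unstimulated scores are 0.551 and 0.541 in Gas, 0.564 and 0.629 in Gai, 0.369 and 0.403 in Gaq, and 0.357 and 0.353 in Ga13 for empty and Cre virus. Each line has its own set of genes, so sizes are not comparable between lines.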

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

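The test of spread between replicate numbers in Gai, the fit of its replicates 2 and 3 alone, the test of differences between responses without each library, the comparison of Cre effects between fibroblast lines, the splits between lines with the replicate number as a block, and the division of splits by the labels they kept were chosen after the results they concern were seen.

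Effects differed between groups in 6 tests. The TRAP-6 response differed between Cre and empty virus for 25 genes in Gaq and 13 in Ga13. It differed between lines for 23 genes (Gaq against Gai) and 53 genes (Ga13 against Gai), or 161 and 288 with the replicate number as a block. The mean effect of Cre differed between Gaq and Gai for 98 genes (55 higher and 43 lower in Gaq) and between Ga13 and Gaq for 102 (42 higher and 60 lower in Ga13), while edgeR found 0 between Ga13 and Gai (500 at an unadjusted p under 0.05, 0 by DESeq2). With the block these 3 counts were 479, 631 and 4. Chosen after their values were seen, the matrix gene Efemp1 had a Cre effect 0.58 ± 0.08 higher in Gaq than in Gai (edgeR adjusted p = 1.32e-05), and Pdzd2 had an effect 0.91 ± 0.12 higher (edgeR adjusted p = 1.32e-05).

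In Gaq fibroblasts Cre changed 411 genes without agonist and 529 with agonist. An effect of Cre or virus common to the lines is argued against as the whole cause by the same genes in Gai and Ga13, whose median change was at most 0.130 of that in Gaq. These genes were chosen by their change in Gaq, which may enlarge that change and lower this ratio. A smaller common part stays open, since 59.5% and 70.1% of these genes went the same way in Gai and Ga13 without agonist (correlation 0.240 and 0.359), and 71.3% and 64.3% with agonist (0.596 and 0.275). Depth, GC content and a single library are argued against as the whole cause, since the counts stayed at 0.946, 1.12 and 0.535 times the full ones or more. Thinning to the smallest library gave 389 and 501 genes, of which 366 and 468 were called before. Removing each library's GC trend gave 463 and 578, against 405 and 514 called genes with a GC value. Without any 1 library the lowest counts were 262 and 283. A shift in cell type mix stays open, because mesothelial markers were higher by a median of at least 0.257 in both states. Of these markers 5 of 6 stood at 10 CPM or more in Gaq, with Upk1b highest at 245 CPM. The rise is not particular to Gaq, since the mesothelial list was also higher with Cre in both states of Gai. There 0 genes were called in either state without the block. The biosensor may oppose TRAP-6 type signalling at rest, where the score of rising Ga13 TRAP-6 genes differed by -0.0758 ± 0.0208 (SE). With 3 libraries against 3 this stays open. The stimulated difference of 0.0326 ± 0.00571 argues against it with agonist, and over both states, where these 2 differences oppose each other, exact permutation p = 0.32. Falling Ga13 TRAP-6 genes, which it would raise, differed by -0.0150 ± 0.00869 at rest and -0.00662 ± 0.00834 with agonist (exact permutation p = 0.09 over both states). This goes the other way, within 2 SE.

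TRAP-6 changed 179 genes in Gai against 871 in Gaq and 1327 in Ga13. A smaller response of the same genes fits: genes called in Gaq and Ga13 moved in Gai by a median of 0.583 of their mean there. Those genes were chosen by the changes in the divisor, which pulls this ratio down. Divided by the line not used to choose genes, the ratio was 0.625 of Ga13 for genes called in Gaq. It was 0.652 of Gaq for genes called in Ga13. In all 3 comparisons 87.4% or more of the genes went in the same direction. Spread between replicate numbers fits too, since the count with the replicate number as a block was 4.45 times that without. This spread lies mainly between the libraries numbered 1 and the others. In the 4 Gai groups the chi-square per gene was 9.71 to 19.3 for pairs with replicate 1, and 2.99 to 3.44 between replicates 2 and 3, which alone gave 703 genes. The Gai cultures also held more RNA of several macrophage markers than Gaq and Ga13 (Lyz2 1166, 445 and 217 CPM, Itgam 41.8, 12.8 and 5.93 CPM, C1qb 19.1, 8.16 and 4.40 CPM), though not of all markers listed. These genes were chosen after their values were seen and their levels were not compared by a test, so a difference in cell mix stays open. All of these may contribute, and lines and cultures were not separated by the design.

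Where the TRAP-6 response differed between viruses, the difference (Cre minus empty) was mostly positive, in 24 of 25 genes in Gaq and 12 of 13 in Ga13. The counts moved without most libraries. In Ga13 as little as 0.231 of the count was left, and only leaving out unstimulated empty 2 or unstimulated Cre 3 kept it within 1.5 times. In Gaq as little as 0.28 was left, and only unstimulated empty 2 and 3, unstimulated Cre 2, and stimulated empty 2 and 3 could be left out within 1.5 times. By the rule fixed beforehand, on the share of the count left, Ga13 met the mark for a single library as the cause. Gaq lay between the marks of that rule and stays undecided by it. A test chosen after these counts were seen argues against a single library as the whole cause, since the differences themselves stayed. Without any 1 library their median ratio to the full fit was at least 0.924 in Gaq and in Ga13, and the lowest ratio of any gene was 0.817 in Gaq and 0.811 in Ga13. The largest unadjusted p was 0.000629 in Gaq and 0.000389 in Ga13, so calls ended at the adjustment for the number of genes. A lower level at rest with Cre may underlie the Gaq differences, where 0.6 of the genes differed more at rest (95% interval 0.387 to 0.789), which decides nothing. In Ga13 that share was 0.308 (95% interval 0.0909 to 0.614), so most of the called genes differed more with agonist. Both intervals treat genes measured in the same libraries as independent and may be too narrow. The median difference (Cre minus empty) of the Ga13 genes was -0.159 at rest and 0.207 with agonist, so a lower level at rest stays open there too. No other biological explanation was tested, and effects of the biosensor and of Cre itself are not separated.

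Other splits of the same libraries were fitted for each count. For the mean agonist response 1 of 100 splits, the real split, gave as many genes in Gas (4211, highest other 102), Gaq (871, highest other 137) and Ga13 (1327, highest other 203). This share is under 0.05 and argues against chance. In Gai 3 of 100 did (179, highest other 924), a share also under 0.05, though other splits gave more genes than the real one. These shares are not adjusted over the counts tested. The Gai splits with 924 and 530 genes kept libraries of the same number together and point to a structure of the samples by replicate number, and among the 15 other splits that parted all 6 pairs the highest was 0. For the difference between responses, 1 of 100 splits gave 13 or more in Ga13 (highest other 9), a share under 0.05 before such adjustment. In Gaq 10 of 100 gave 25 or more (highest other 1010), which leaves chance undecided. The 9 other Gaq splits among these kept unequal numbers of virus labels in the 2 states, which carries the Cre effect itself into the difference, so they are a poor measure of chance. Among the 38 other Gaq splits that kept equal numbers the highest was 1. In Gas and Gai, where the real count was 0, 100 of 100 splits gave as many (highest other 42 and 336). Between lines, 1 of 40 splits gave 23 or more for Gaq against Gai (highest other 19, which kept 4 labels in each line). For Ga13 against Gai 2 of 40 gave 53 or more (highest other 55), so only the former share was under 0.05. These splits mix stimulated with unstimulated libraries, which breaks up the TRAP-6 response of each line. They test for no response in either line, not for equal responses, so they do not decide whether chance explains a difference between lines. The split with 55 kept 8 labels in Ga13 and 6 in Gai, and among the 17 other splits that kept equal numbers the highest was 1. For Ga13 against Gaq 40 of 40 gave 0 or more (highest other 0). These fits ignore the pairing of Gai libraries. With the replicate number as a block, and labels exchanged within it, 1 of 40 gave 161 or more for Gaq against Gai (highest other 2). For Ga13 against Gai 1 of 40 gave 288 or more (highest other 198, which kept 0 labels in Ga13 and 4 in Gai). Both shares were under 0.05, but these splits break up the response too and do not decide about a difference between lines. For Ga13 against Gaq 5 of 40 gave 7 or more, which for the same reason leaves chance undecided. Among the 4 other splits there that kept equal numbers of labels the highest was 0. The highest of all other splits for this pair, 1560, kept 0 of 12 labels in Ga13 and 10 of 12 in Gaq. This carries the TRAP-6 response into the difference.

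The remaining counts allow 10 splits each, too few for a share under 0.05. With empty virus the real response counts were 2653, 19, 411 and 614 in Gas, Gai, Gaq and Ga13, with 0 the highest other in each. With Cre they were 2583, 38, 523 and 851 (highest other 0, 0, 1 and 1). For Cre against empty without agonist they were 1, 0, 411 and 2 (highest other 3, 0, 1 and 0), and as many genes were called in 5, 10, 1 and 1 splits. With agonist they were 3, 0, 529 and 9 (highest other 4, 0, 1 and 1), in 2, 10, 1 and 1 splits.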

How the results depend on the processing

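The fits of Gai replicates 2 and 3 alone and without the Gai libraries numbered 1, all values of the Cre effect between lines, and the score test within replicate numbers, were chosen after seeing the data.

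RLE scaling moved none of the 34 summary results it was applied to, a score limited to genes of at least 2-fold or with a prior count of 0.5 moved none of 4 each, and no named gene result of 354 reversed. Of these, 75 were lost in at least 1 fit without a library, 14 with DESeq2, 1 with RLE and 0 with the block. Of 91 list calls 11 held with an estimated correlation, 49 with fry, 91 with RLE, 88 with the block and 90 with a prior count of 0.5.

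Without a filter on low counts, Cre against empty gave 13 genes in unstimulated Gas. In Gai the counts were 133 (response, empty virus), 202 (response, Cre), 445 (mean response), 6 and 9 (Cre against empty without and with agonist) and 2 (difference between responses). The difference between responses gave 67 in Gaq and 86 in Ga13, and Cre against empty in Ga13 gave 33 and 63. Between lines the TRAP-6 response gave 57 (Gaq against Gai), 121 (Ga13 against Gai) and 2 (Ga13 against Gaq), and the Cre effect 191 (Gaq against Gai) and 248 (Ga13 against Gaq). A mean CPM of at least 1 gave 1 gene for unstimulated Cre in Ga13. Fits of only the compared groups gave 0 for stimulated Cre in Gas and 4 for unstimulated Cre in Ga13.

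DESeq2 gave 81, 106 and 288 genes for the Gai responses (empty virus, Cre, mean) and 1 and 2 for Cre against empty. It gave 40 and 60 for the difference between responses in Gaq and Ga13, and 7 and 30 for Cre against empty in Ga13. Between lines it gave 46 and 90 for the TRAP-6 response (Gaq and Ga13 against Gai) and 178 and 201 for the Cre effect (Gaq against Gai, Ga13 against Gaq). Shared genes were 84 for Gas and Gai, 207 for Gai and Ga13, and 55 for both viruses in Gai. With an adjusted p under 0.01 they were 28 for Gas and Gai, 275 for Gas and Ga13, 69 for Gai and Gaq, 70 for Gai and Ga13, 9 for both viruses in Gai and 110 for Gaq Cre in both states. With only rising genes the score difference was 0.0793 in Gaq and 0.0252 in Ga13. With virus labels exchanged within replicate numbers no score difference passed (exact permutation p = 0.375 to 0.625).

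With the replicate number as a block, Gai gave 254, 355 and 797 genes for the responses and 11 and 9 for Cre against empty, and its biological coefficient of variation was 0.0533 in place of 0.0911. The block gave 762 (response, empty virus), 752 and 944 (Cre against empty) and 91 (difference) in Gaq, and 1357 (response, Cre), 33 and 112 (Cre against empty) and 138 (difference) in Ga13. Between lines it gave 161, 288 and 7 for the TRAP-6 response (Gaq against Gai, Ga13 against Gai, Ga13 against Gaq) and 479, 4 and 631 for the Cre effect. Gai replicates 2 and 3 alone gave 222, 289 and 703 for the responses (336 rising and 367 falling in the mean response) and 14 and 8 for Cre against empty. Without the Gai libraries numbered 1 the TRAP-6 response differed for 132 and 279 genes (Gaq and Ga13 against Gai). For all these alternatives the cause was not tested.

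Each library was left out in turn, and within a line the ranges cover only libraries of the groups that a contrast compares. In Gas the counts ranged from 2058 to 2459 (response, empty virus), 2219 to 2417 (Cre), 3650 to 4251 (mean), 1 to 4 and 0 to 2 (Cre against empty without and with agonist) and 0 to 0 (difference). In Gai they ranged from 10 to 23, 15 to 52, 124 to 239, 0 to 0, 0 to 3 and 0 to 0 in that order. In Gaq they ranged from 261 to 491, 333 to 486, 693 to 989, 262 to 523, 283 to 592 and 7 to 43. Without a Gaq library of the other groups, the count of Cre against empty with agonist reached 642. In Ga13 they ranged from 456 to 510, 592 to 855, 1051 to 1308, 0 to 3, 3 to 15 and 3 to 22. Between lines they ranged from 5 to 49 (Gaq against Gai), 33 to 104 (Ga13 against Gai) and 0 to 0 (Ga13 against Gaq). Score differences ranged from -0.0328 to 0.00801 in Gas, 0.0272 to 0.0998 in Gai, 0.0250 to 0.0491 in Gaq and -0.0131 to 0.00606 in Ga13.

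Thinning every Gaq library to the smallest gave 389 and 501 genes for Cre against empty without and with agonist, in place of 411 and 529, so depth changed these counts little. Simulated data had 3 replicates at these depths, with depth not varied and no structure by replicate number. There 1.5-fold differences between responses were recovered for 44.8% of genes in Gas, 34.3% in Gai, 37.3% in Gaq and 65.7% in Ga13.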

Other observations

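The genes named in this part were chosen after their values were seen.

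Marker gene levels were read as a rough sign of which cells the cultures held. In Gas cultures 12 of 13 astrocyte markers stood at 10 CPM or more, with a median of 406 CPM and the filament protein gene Gfap highest at 3852 CPM. Markers of other cells were also present there, with the oligodendrocyte factor Olig1 at 510 CPM, the macrophage lysozyme gene Lyz2 at 176 CPM, the smooth muscle actin gene Acta2 at 2089 CPM, the cilia factor Foxj1 at 331 CPM and the neuronal Stmn2 at 91.9 CPM. In each of the fibroblast lines 11 of 12 fibroblast markers stood at 10 CPM or more. So did 5 of 6 mesothelial and 6 of 9 measured smooth muscle markers in each, with Acta2 at 2976 CPM in Gai, 1544 in Gaq and 2437 in Ga13. Of the measured macrophage markers 14 of 16 did so in Gai, 7 of 15 in Gaq and 4 of 15 in Ga13.

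In astrocytes the neuron markers that rose with isoproterenol were the neurofilament gene Nefl (3.12 ± 0.24), the GABA synthesis gene Gad1 (1.88 ± 0.10) and the tubulin gene Tubb3 (0.16 ± 0.05). The cAMP list genes that fell were the clock gene Per2 (-0.75 ± 0.06) and the CREB coactivator gene Crtc3 (-0.56 ± 0.05).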
